A study of Mus musculus with 12 samples.

How the data were processed

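The table analysed holds 1 value per gene and library for 12 mouse hippocampus libraries in 4 groups of 3. Per the labels' protocols, hippocampi were dissected and snap-frozen, RNA was isolated with a column kit, and libraries were made from total RNA with a stranded kit after ribosomal RNA depletion. The submitters' processing notes name CASAVA, kallisto and sleuth and the mouse build mm10, without versions, roles or order. The annotation release and the step from transcripts to genes are not given in the sources used here. The deposited table is named by the authors as TPM, which by definition has 1 fixed sum per library, but its columns sum to between 973187 and 1024536, so each library carries a further factor from the authors. The values were therefore treated as a deposited signal that is proportional to TPM within a library, rather than as plain TPM as the design had assumed; the test is the same for both. The ratios of the libraries to their geometric mean had medians between 0.994 and 1.01, so little scaling difference remained. TPM keeps no trace of read counts, so depth is unknown, no counting interval or detection limit is given, and a value of exactly 0 can be a failed estimate. No 2 libraries held identical values, and Spearman correlations between libraries ran from 0.947 to 0.951.

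All 12 value columns were matched to samples by their names, with 0 left over. Groups come from the sample titles and tags. The labels do not say whether mice of a group came from separate litters or cages, and enriched mice were caged with littermates, so p values measure the spread between these libraries, which can be smaller than that between litters. The labels do not give the sex of each mouse or the hour of killing. As a check, 4 Y-linked genes were present at similar levels in every library, so each held male tissue and none came from females alone. The table has 0 rows for Xist, so a part of female tissue could not be checked. Gene symbols, positions and biotypes were taken from GENCODE M21 on GRCm38, the assembly that mm10 names; 35827 of 36119 identifiers had a symbol. The table holds 13490 pseudogenes, and 14109 of the genes tested are protein-coding and 761 pseudogenes. Values of retrogenes and pseudogenes (Rps27rt, Gm44922, Gm12854, Gm6741) are uncertain, since kallisto divides reads among near-identical copies by estimate.

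Values were analysed as log2(TPM + 0.5) for the 14947 genes with a mean of at least 1 over the 12 libraries. Fold changes on this scale understate the change of low genes. limma 3.58.1 in R 4.3.3 fitted a mean per group to all 12 libraries at once (8 residual degrees of freedom, 3.82 added by the prior), with a mean-variance trend in the empirical Bayes step, and 8 contrasts were tested: ethanol in each housing, enrichment in saline and in ethanol mice, both against neither, the interaction, and ethanol and enrichment averaged over the other factor. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. On data simulated for ethanol in standard housing over 14947 genes, the test called 81% of 100 genes changed by 2-fold and 95% of 100 changed by 4-fold, 5.9% of its calls were unchanged genes, and it called 0 genes when nothing was changed. The simulated genes varied independently, with normal noise, so these rates do not cover genes that move together. Other splits of the real libraries called up to 2 genes for this comparison and up to 15 for ethanol averaged over housing.

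Gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. The 38 lists with at least 3 tested genes cover neuronal signalling, activity and growth factors, stress and immune responses, chromatin, the circadian clock, hippocampal and neighbouring cell types, and ribosomal, mitochondrial and histone genes. Lists were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 38 lists of a comparison. None of the calls held when the correlation was estimated from the data. The number of list members that passed is given adjusted over all genes and adjusted over the list alone. The mean log2 fold change of a list is the mean over its tested members. The sex-linked list served as a check only, and a list of small structural RNAs had too few genes in the table.

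The genes named are, for each comparison, the 10 largest rises and falls among called genes whose libraries do not overlap between groups, leaving out unnamed predicted genes. Where fewer than 10 passed, the 5 smallest p values in each direction were added and are said not to pass. The 3 members of each called list with the smallest p in the direction of the call were also eligible, and 10 genes were fixed for every comparison of 2 groups (Bdnf, Fos, Arc, Egr1, Npas4, Nr4a1, Dcx, Ttr, Gfap and Mbp). Members that passed over a list alone, Cirbp, Hspa1a and Icam1 per library, and the other genes given per library in the closing section were chosen after their values were seen. Results for some genes that the rule covers are not reported here.

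Alternatives were pseudocounts of 0.1 and 1, no filter, a mean of at least 5, median-ratio scaling, the replicate number as a block, robust empirical Bayes, only the groups compared, an estimated correlation, fry, and leaving out each library in turn. Protein-coding genes only, leaving out standard saline replicate 2 and enriched saline replicate 2 together, and an exact permutation of list means were added after seeing the data. So was leaving out enriched saline replicate 2 in comparisons without its group. Correlations of effects were set beside 1000 simulated sets of unchanged groups. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.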

Results

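Hippocampal RNA was measured in 12 adult C57BL/6 mice at postnatal day 70, with 3 mice in each of 4 groups. As pups they had received ethanol at 2.5 g/kg under the skin, or saline alone, in 2 injections given 2 hours apart on each of postnatal days 6 and 7. From day 21 they lived in standard cages or in enriched cages, which held 2 to 6 littermates of 1 sex with running wheels, toys and extra nesting material. The groups are called standard saline, standard ethanol, enriched saline and enriched ethanol below. The series sets early alcohol, as a model of human exposure before birth, beside later enrichment, and its labels call the ethanol exposure prenatal although the protocol places every injection after birth. Values are the deposited TPM, which summed to between 973187 and 1024536 per library, and the sequencing depth is unknown. Of 36119 genes in the table, 14947 had a mean of at least 1 and were tested with limma. The Y-linked gene Ddx3y lay between 38.5 and 47.0 in all 12 libraries, and Uty between 20.7 and 27.3.

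Some libraries stood apart in cell type markers before any comparison was made. Ttr, the transthyretin gene of the choroid plexus, was at 7503 in enriched saline replicate 2 and at 385 in standard ethanol replicate 1, and between 20.8 and 118 in the other 10 libraries. Standard saline replicate 2 had the highest mean of the dentate granule cell markers, 0.56 above the 12-library mean on the log2 scale. Its means were the lowest for the markers of myelin (-0.41), meningeal fibroblasts (-0.90), neocortex and subiculum (-0.53), striatum (-0.44), thalamus and habenula (-0.31) and astrocytes (-0.16). Its immediate-early mean was also the lowest (-0.48), with Fos at 5.13 against 17.4 to 44.8 elsewhere. Enriched ethanol replicates 1 and 2 had the highest means of the unfolded protein and heat shock list (0.36 and 0.40), while replicate 3 lay at -0.06. The plot of list means shows these libraries beside the groups.

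**Figure D1:**
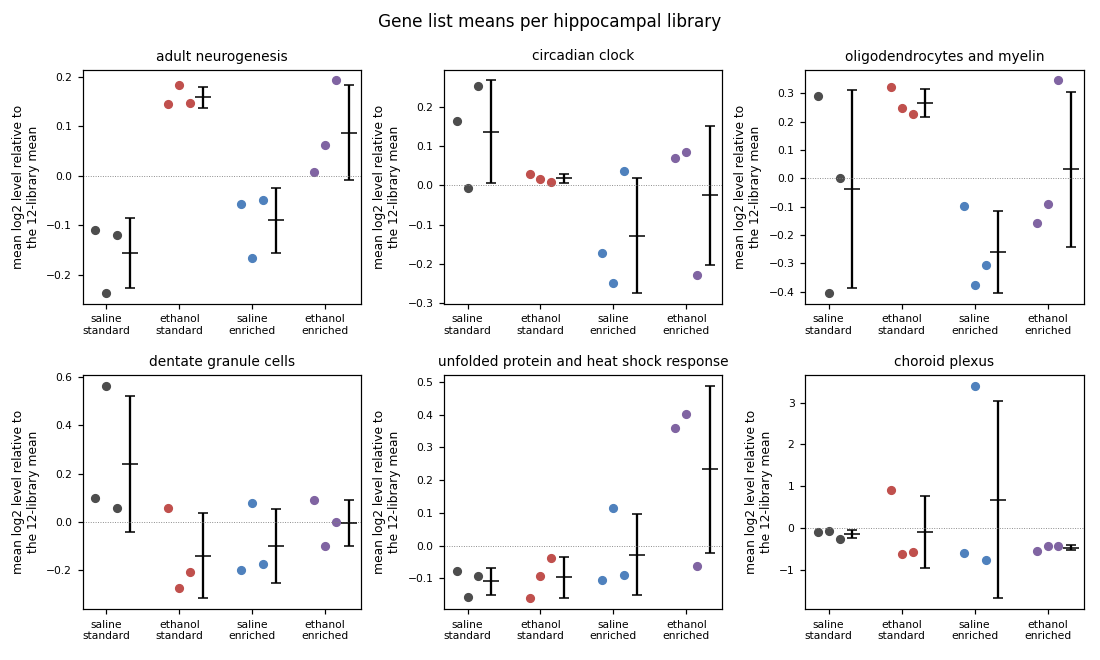
Each panel plots, for 1 gene list, the mean log2(TPM + 0.5) of its tested members in each of the 12 libraries relative to the mean over all 12 (vertical axis) by group (horizontal axis); points are libraries and the bar beside them is the group mean ± SD (n = 3). All 6 ethanol libraries lie above all 6 saline libraries for adult neurogenesis (0.007 to 0.193 against -0.237 to -0.049), and enriched saline replicate 2 reaches 3.41 for choroid plexus.

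The first comparison asks what early ethanol left in the adult hippocampus of standard-housed mice. Some genes of newborn neurons were higher in standard ethanol than in standard saline mice. Doublecortin (Dcx), a microtubule protein of migrating young neurons on chromosome X (143855842 to 143933311, GRCm38), averaged 8.85 ± 0.966 TPM in ethanol mice (SD, n = 3) and was at 5.46, 4.06 and 6.04 in saline mice (log2 fold change 0.73, SE 0.14). The transcription factor Sox11 of immature neurons averaged 11.2 ± 0.506 against 7.90 ± 0.780, and Igfbpl1, a marker of neuronal progenitors, 3.39 ± 0.455 against 1.10 ± 0.640. Of the 23 tested members of the adult neurogenesis list, 5 rose (Dcx, Sox11, Sox4, Igfbpl1 and Dpysl3) and 1 fell (Hes5, a Notch target of progenitors, log2 fold change -0.59) when adjusted over the list alone. None passed when adjusted over all genes tested. The list's mean log2 fold change was 0.31 (camera, Benjamini-Hochberg adjusted p = 1.45e-06; adjusted p = 0.121 with an estimated correlation), and fry, which tests movement in a common direction, gave an adjusted p of 0.0389.

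Markers of mature dentate granule cells went the other way. Trpc6, a cation channel, averaged 29.0 ± 1.22 in standard ethanol and 45.2 ± 7.20 in standard saline mice. Of the 12 tested markers 6 fell when adjusted over the list alone (Trpc6, Plk5, C1ql2, Lct, Stxbp6 and Dsp), with none rising and none passing over all genes. The mean log2 fold change of these markers was -0.38 (camera adjusted p = 1.45e-06; adjusted p = 0.720 with an estimated correlation). It was -0.22 without standard saline replicate 2, the library with the highest granule cell mean (camera adjusted p = 0.00607). Myelin and oligodendrocyte markers averaged a log2 fold change of 0.30 (camera adjusted p = 3.53e-05; adjusted p = 0.988 with an estimated correlation), with 1 of 20 members, the myelin tight junction gene Cldn11, rising over the list alone. Oligodendrocyte precursor markers averaged 0.29 (camera adjusted p = 1.20e-04; adjusted p = 0.720 with an estimated correlation), with Gpr17, Enpp6 and Olig1 of 10 rising over the list alone. Meningeal fibroblast markers averaged 0.51 (camera adjusted p = 7.86e-05; adjusted p = 0.894 with an estimated correlation), with the collagens Col3a1 and Col1a1 and the proteoglycan Dcn of 13 rising over the list alone. Standard saline replicate 2 had the lowest means for myelin and fibroblast markers, and without it the mean log2 fold changes were 0.12 and 0.25 (camera adjusted p = 0.323 and 0.214), while without standard saline replicate 1 they were 0.47 and 0.79. Among 25 interferon response genes Ifit3 was the 1 that fell over the list alone (log2 fold change -0.77). The interferon list averaged -0.10 and the clock list -0.12 (camera adjusted p = 0.0485 and 0.0392; adjusted p = 0.988 with an estimated correlation for each). Neither call held without standard saline replicate 1 (0.314 and 0.132), standard saline replicate 3 (0.298 and 0.350) or standard ethanol replicate 1 (0.328 and 0.0535), nor the clock call without standard ethanol replicate 3 (0.112). Without standard saline replicate 2 the means were -0.22 and -0.19. Endothelial markers averaged 0.15 and mural cell markers 0.37 (camera adjusted p = 0.0250 and 0.00114; adjusted p = 0.988 and 0.720 with an estimated correlation). Without standard saline replicate 3 neither call held (0.262 and 0.0523), nor the endothelial call without standard saline replicate 2 (0.119) or standard ethanol replicate 3 (0.120). The endothelial mean was 0.22 without standard saline replicate 1. Cytosolic ribosomal protein genes averaged -0.05 (camera adjusted p = 0.00206; adjusted p = 0.988 with an estimated correlation), a call that did not hold without standard saline replicate 1 (mean 0.02, camera adjusted p = 0.533) or standard ethanol replicate 1 (0.904). The mean was -0.09 and -0.08 without the replicates 3 of standard saline and standard ethanol.

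Single genes rarely passed in standard-housed mice. limma called 2 of the 14947 genes at a Benjamini-Hochberg adjusted p under 0.05. At an unadjusted p under 0.05 there were 1105, where chance gives 747.4 on average. Genes are not independent, so chance can give counts well away from that average. Unadjusted counts were not taken over other splits of the libraries, so no excess is read from them. Both called genes were low and listed at 0 in whole groups. The pseudogene Gm44922 (chromosome 11, 73413319 to 73413408) was listed at 8.47, 8.41 and 8.35 in the 3 standard saline libraries and at 0 in the other 9 (limma adjusted p = 5.67e-05). The gene ENSMUSG00000118641, which has no name or position in the annotation used here, was listed at 10.4, 5.69 and 4.41 in the 3 standard ethanol libraries and at 0 in the other 9 (limma adjusted p = 0.00111). The next smallest p values did not pass. They belonged to Plat, the tissue plasminogen activator (38.6 ± 1.31 in ethanol against 29.6 ± 0.304 in saline mice, limma adjusted p = 0.195), Igfbp3, Marcks and Plagl1 (log2 fold changes 0.58, 0.40 and 0.79), and on the lower side Rps27rt, Map7, Trpc6 and the spliceosome gene Snrpb (limma adjusted p from 0.244 to 0.269). None of the fixed genes passed, and Dcx had a limma adjusted p of 0.269. Npas4, Fos, Egr1, Arc, Nr4a1, Mbp, Gfap and Bdnf had log2 fold changes of 0.78, 0.88, 0.38, 0.23, 0.17, 0.17, 0.02 and 0.01, and Ttr -0.33 with an SE of 1.70. Without standard saline replicate 2, Npas4, Fos, Egr1, Arc and Nr4a1 had 0.39, 0.055, -0.015, -0.25 and -0.27. The count of called genes was 7 without standard saline replicate 2 and 4 without standard saline replicate 1.

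In enriched cages the same question was put to enriched ethanol against enriched saline mice. Gfap, the intermediate filament of astrocytes (chromosome 11, 102887336 to 102900912), averaged 257 ± 17.6 in enriched ethanol and 179 ± 20.2 in enriched saline mice (log2 fold change 0.52, SE 0.09; limma adjusted p = 0.383), and it was the 1 astrocyte gene of 16 that rose when adjusted over the list alone. Sox11 was at 11.6 to 12.5 against 8.10 to 9.08 and was the 1 neurogenesis gene of 23 that rose over the list alone, while Dcx, with 8.21 ± 0.225 against 7.13 ± 0.440, did not pass. The neurogenesis list averaged a log2 fold change of 0.18 (camera adjusted p = 0.0219; adjusted p = 0.648 with an estimated correlation), and its camera adjusted p was 0.148 without enriched saline replicate 2 and 0.296 without enriched ethanol replicate 3. Myelin markers averaged 0.29 (camera adjusted p = 8.02e-06; adjusted p = 0.648 with an estimated correlation), with Fa2h, an enzyme of myelin lipid synthesis, rising over the list alone. Astrocyte markers averaged 0.13 (camera adjusted p = 0.00268; adjusted p = 0.648 with an estimated correlation). Without enriched ethanol replicate 3 neither call held (0.0586 for myelin, with a mean of 0.14, and 0.0525 for astrocytes). Immediate-early genes averaged 0.18 and postsynaptic density genes 0.13 (camera adjusted p = 3.72e-04 for each; adjusted p = 0.648 with an estimated correlation for each), and no member of either list passed over the list alone. The immediate-early mean was 0.09 without enriched ethanol replicate 2 and 0.29 without replicate 3, and the postsynaptic mean 0.08 without enriched ethanol replicate 1. Glucocorticoid response genes averaged 0.14 (camera adjusted p = 0.00417; adjusted p = 0.648 with an estimated correlation), with Ddit4 and Errfi1 of 21 rising over the list alone, and 0.22 without enriched ethanol replicate 3 and 0.06 (camera adjusted p = 0.0897) without enriched saline replicate 3. Unfolded protein and heat shock genes averaged 0.26 and inflammatory genes 0.42 (camera adjusted p = 2.19e-04 and 0.0201; adjusted p = 0.648 with an estimated correlation for each). The heat shock mean was 0.41 without enriched ethanol replicate 3, and the inflammatory call did not hold without enriched saline replicate 1 (0.228) or enriched ethanol replicates 1 (0.0709) or 2 (0.0747). Its mean was 0.63 without replicate 3. DNA methylation and chromatin enzymes averaged 0.09 and cytosolic ribosomal protein genes -0.04 (camera adjusted p = 0.0354 and 0.0211; adjusted p = 0.648 and 0.749 with an estimated correlation). Neither call held without enriched saline replicate 2 (0.148 and 0.659) or enriched ethanol replicates 1 (0.180 and 0.883) or 3 (0.0586 and 0.0652), nor the chromatin call without enriched saline replicate 1 (0.119) or the ribosomal one without enriched saline replicate 3 (0.0842). The ribosomal mean was -0.07 without enriched saline replicate 1 and -0.08 without enriched ethanol replicate 2.

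limma called 0 genes in enriched cages at an adjusted p under 0.05, against 1160 at an unadjusted p under 0.05. The smallest p values, none of which passed (limma adjusted p from 0.383 to 0.527), were those of Rab8a, Gfap, Dcun1d3, Map1a and Gm11027 on the higher side and Mtf2, Adcyap1, Gm6710, Tcerg1l and Pop7 on the lower side. Map1a, a microtubule-associated protein, averaged 422 ± 17.2 against 313 ± 4.19, and Adcyap1, which encodes the neuropeptide PACAP, 7.20 ± 0.134 against 11.4 ± 2.13. Gm11027 was listed at 0 in all 3 enriched saline libraries and at 5.60, 3.03 and 10.9 in the enriched ethanol libraries. Arc, Mbp, Egr1, Nr4a1, Fos, Bdnf and Npas4 had log2 fold changes of 0.73, 0.35, 0.28, 0.18, 0.09, 0.05 and 0.00, and Ttr -2.77 with an SE of 1.70. The choroid plexus list averaged -1.14 (camera adjusted p = 0.00143; adjusted p = 0.749 with an estimated correlation), and 0.22 without enriched saline replicate 2 (camera adjusted p = 0.341) and -1.79 and -1.86 without enriched saline replicates 1 and 3. Without enriched ethanol replicate 3, 15 genes were called, and without enriched saline replicate 1, enriched saline replicate 3 or enriched ethanol replicate 2, there were 2, 1 and 1.

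Averaged over housing, ethanol was tested with 6 libraries against 6. Adjusted over the list alone, 7 of the 23 tested adult neurogenesis genes rose (Sox11, Dpysl3, Dcx, Igfbpl1, Ccnd2, Sox4 and the cell cycle kinase Cdk1), Hes5 fell, and none passed over all genes. Sox11 (chromosome 12, 27334264 to 27342574) came closest, with a log2 fold change of 0.47 (SE 0.07; limma adjusted p = 0.101), followed by Plat (0.28, SE 0.04; limma adjusted p = 0.101). The list averaged 0.25 (camera adjusted p = 8.69e-07; adjusted p = 0.118 with an estimated correlation; fry adjusted p = 0.0300). Its mean per library lay above every saline library in all 6 ethanol libraries. An exact permutation test of the list mean within housing, two-sided, gave p = 0.005, the smallest its 400 arrangements can give (adjusted over 38 lists, 0.190). The test was chosen after the data were seen, and such a full separation fixes its p at that minimum. Other lists that camera called for this average had larger p in the same test. It was 0.045 for myelin (adjusted, 0.475), 0.09 for mural, 0.175 for heat shock, 0.205 for immediate-early and 0.365 for ribosomal protein genes. No list passed after adjustment. Myelin markers averaged 0.30 (camera adjusted p = 2.15e-09; adjusted p = 0.645 with an estimated correlation), and 8 of 20 rose over the list alone, among them Cldn11 (0.65, SE 0.14) and Fa2h (0.61, SE 0.14). Precursor markers Gpr17, Enpp6 and Olig1 also rose over their list of 10 alone, and that list averaged 0.16 (camera adjusted p = 8.79e-04; adjusted p = 0.645 with an estimated correlation), or 0.10 without enriched ethanol replicate 3. Ifit3 and Ifi27 fell over the interferon list alone (log2 fold changes -0.53 and -0.34; list camera adjusted p = 0.0133; adjusted p = 0.645 with an estimated correlation). The list's call did not hold without standard saline replicates 1 (0.0517) or 3 (0.0737) or standard ethanol replicate 1 (0.0514), while its mean was -0.17 without standard saline replicate 2. limma called the 2 genes named for standard cages, Gm44922 and ENSMUSG00000118641, with 1199 genes at an unadjusted p under 0.05. Of the other genes with the smallest p, Tmsb15b2 and Sparc were higher and Mtf2, Rbm3, Ifit3b and Trpc6 lower in ethanol mice, with limma adjusted p = 0.244 for each. Without enriched ethanol replicate 3, 10 genes were called, and 1 without any of standard saline replicates 1 and 3, the 3 standard ethanol libraries, enriched saline replicate 2 and enriched ethanol replicate 1.

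Camera called 13 lists for this average, none of them with an estimated correlation. Dentate granule cell markers averaged -0.14 (camera adjusted p = 0.0135; adjusted p = 0.762 with an estimated correlation), with Trpc6, Plk5 and C1ql2 falling over the list alone. The camera adjusted p was 0.369 without standard saline replicate 2, 0.0794 without standard ethanol replicate 2, 0.0619 without enriched saline replicate 2 and 0.0537 without enriched ethanol replicate 2. Immediate-early genes averaged 0.17 (camera adjusted p = 3.95e-05; adjusted p = 0.645 with an estimated correlation), and 0.08 without standard saline replicate 2. Mural cell markers averaged 0.22 (camera adjusted p = 0.00597; adjusted p = 0.645 with an estimated correlation), and this call held without any 1 library. Gfap of the 16 astrocyte genes rose over the list alone, with list means of 0.09 for astrocytes and 0.14 for unfolded protein and heat shock genes (camera adjusted p = 0.00597 and 0.00215; adjusted p = 0.645 with an estimated correlation for each). For Gfap the log2 fold change in standard cages was only 0.02, and -0.07 without standard saline replicate 2. The astrocyte call did not hold without standard saline replicate 2 (0.137), and the heat shock mean was 0.21 without enriched ethanol replicate 3. In standard cages the heat shock mean was 0.01 (camera adjusted p = 0.909), and enriched ethanol replicates 1, 2 and 3 lay at 0.36, 0.40 and -0.06 relative to the 12-library mean. Choroid plexus markers averaged -0.55 and ependymal markers 0.19 (camera adjusted p = 0.0301 and 0.0474; adjusted p = 0.825 and 0.762 with an estimated correlation). The choroid plexus mean was 0.13 without enriched saline replicate 2 (camera adjusted p = 0.358) and -0.87 and -0.91 without enriched saline replicates 1 and 3. Its call did not hold without standard saline replicate 2 (0.0909), standard ethanol replicates 2 (0.136) or 3 (0.108) or enriched ethanol replicate 2 (0.0513) either. The ependymal mean was 0.34 without enriched saline replicate 2. Its call did not hold without standard saline replicates 1 (0.0517) or 2 (0.154), standard ethanol replicate 1 (0.192), enriched saline replicates 1 (0.0866) or 3 (0.383) or enriched ethanol replicate 3 (0.211). DNA methylation and chromatin enzymes averaged 0.08 (camera adjusted p = 0.0135; adjusted p = 0.645 with an estimated correlation), which did not hold without standard saline replicate 1 (0.0552) or enriched ethanol replicate 1 (0.0681). Cytosolic ribosomal protein genes averaged -0.05 (camera adjusted p = 1.05e-04; adjusted p = 0.825 with an estimated correlation), which did not hold without standard saline replicate 1 (0.271) or standard ethanol replicate 1 (0.0514). Its mean was -0.03 without enriched ethanol replicate 1.

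Enrichment was tested first in saline mice. Clock genes moved in opposite directions. Arntl, which encodes the core clock activator BMAL1 (chromosome 7, 113207465 to 113314126), averaged 34.0 ± 5.01 in enriched saline and 20.7 ± 1.87 in standard saline mice (log2 fold change 0.69, SE 0.12; limma adjusted p = 0.108). Dbp, a transcription factor driven by the clock (chromosome 7, 45705088 to 45710203), averaged 48.1 ± 5.24 against 77.2 ± 8.05 (log2 fold change -0.68, SE 0.11; limma adjusted p = 0.0912). Adjusted over the list alone, 9 of the 18 clock genes fell (Dbp, Ciart, Per3, Per2, Nr1d1, Nr1d2, Tef, Bhlhe40 and Bhlhe41), Arntl rose, and none passed over all genes. The list averaged -0.26 (camera adjusted p = 1.05e-04; adjusted p = 0.774 with an estimated correlation), and fry's test of change in either direction gave an adjusted p of 0.0138.

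In enriched against standard saline mice the lists of astrocyte, myelin and granule cell markers had negative means and the striatal list a positive one, and few members passed over their lists alone. Gfap averaged 179 ± 20.2 against 249 ± 25.5 and was the 1 astrocyte gene of 16 that fell over the list alone (list camera adjusted p = 0.0166; adjusted p = 0.774 with an estimated correlation). The astrocyte mean was -0.11, and -0.19 without standard saline replicate 2, and the call did not hold without standard saline replicates 1 (0.394) or 3 (0.0801). Myelin markers averaged a log2 fold change of -0.22 (camera adjusted p = 6.11e-04; adjusted p = 0.792 with an estimated correlation), and Mbp averaged 1508 ± 117 against 2014 ± 525. The myelin mean was -0.06 without standard saline replicate 1 (camera adjusted p = 0.421) and -0.41 without standard saline replicate 2. Granule cell markers averaged -0.34 (camera adjusted p = 8.80e-05; adjusted p = 0.774 with an estimated correlation), with Dsp falling over the list alone, and -0.18 without standard saline replicate 2 (camera adjusted p = 0.0703). Striatal markers averaged 0.47 with none of 13 passing over the list alone (camera adjusted p = 6.11e-04; adjusted p = 0.118 with an estimated correlation; fry adjusted p = 0.00401). Postsynaptic density genes averaged -0.12 and mitochondrially encoded genes -0.23 (camera adjusted p = 0.00701 and 0.00279; adjusted p = 0.792 and 0.774 with an estimated correlation). Neither call held without standard saline replicate 3 (0.189 and 0.120), nor the postsynaptic call without standard saline replicate 2 (0.280) or enriched saline replicate 2 (0.0914), and the postsynaptic mean was -0.22 without standard saline replicate 1. Meningeal fibroblast markers averaged 0.61 and endothelial markers 0.16 (camera adjusted p = 2.57e-05 and 0.0368; adjusted p = 0.774 and 0.792 with an estimated correlation). The fibroblast mean was 0.35 without standard saline replicate 2, and the endothelial call did not hold without standard saline replicates 2 (0.103) or 3 (0.197) or enriched saline replicate 3 (0.432). Choroid plexus markers averaged 0.82 with all libraries and -0.54 without enriched saline replicate 2 (camera adjusted p = 0.0368 and 0.0154; adjusted p = 0.792 with an estimated correlation and all libraries), and the mean was 1.46 and 1.54 without enriched saline replicates 1 and 3. That call did not hold without standard saline replicates 1 (0.138), 2 (0.0534) or 3 (0.0680).

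limma called 4 genes for enrichment in saline mice, 2 higher and 2 lower, against 1498 at an unadjusted p under 0.05. Of the 4, 3 were listed at 0 in a whole group: Gm12854 in all 6 standard-housed libraries and at 1.58, 1.73 and 4.16 in enriched saline mice, and Gm11027 and Gm44922 in all 3 enriched saline libraries. Rspo2, an enhancer of Wnt signalling (21.6 ± 0.800 against 13.5 ± 1.54), and Cyb561 came next on the higher side without passing (limma adjusted p = 0.0744 and 0.0775), and Rps27rt and Gm29394 on the lower side (0.0775 and 0.0938). Dcx had a log2 fold change of 0.44 (limma adjusted p = 0.376). Npas4, Fos, Bdnf, Nr4a1, Egr1 and Arc had 0.69, 0.67, 0.19, 0.16, 0.05 and -0.10, and Ttr 1.30 with an SE of 1.70. Without standard saline replicate 2, Npas4, Fos, Nr4a1, Egr1 and Arc had 0.30, -0.15, -0.28, -0.34 and -0.57, and Ttr had -1.29 without enriched saline replicate 2. The count was 20 without standard saline replicate 2, 2 without enriched saline replicate 1, and 1 without standard saline replicate 1 or enriched saline replicate 3.

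**Figure D2:**
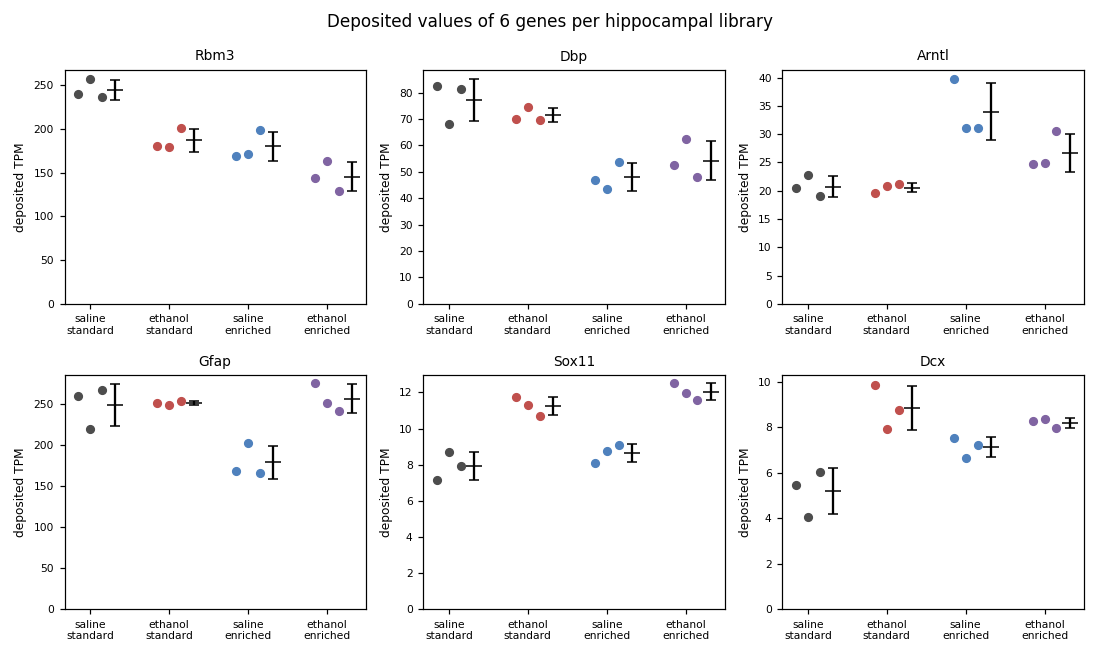
The panels plot the deposited TPM (vertical axis, from 0) of Rbm3, Dbp, Arntl, Gfap, Sox11 and Dcx in the 12 libraries by group (horizontal axis), with points for libraries and a bar for the group mean ± SD (n = 3). Rbm3 averages 245 in standard saline and 146 in enriched ethanol mice, and Sox11 lies between 10.7 and 12.5 in the 6 ethanol libraries and between 7.12 and 9.08 in the 6 saline libraries.

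In ethanol mice, enriched replicates 1 and 2 stood apart from the standard libraries and replicate 3 did not in the same way. Relative to the 12-library mean on the log2 scale, the unfolded protein and heat shock list was at 0.36, 0.40 and -0.06 in enriched replicates 1, 2 and 3 against -0.16 to -0.04 in standard ethanol mice. The myelin list was at -0.16, -0.09 and 0.35 against 0.23 to 0.32. Unfolded protein and heat shock genes averaged a log2 fold change of 0.33 between enriched and standard ethanol mice (camera adjusted p = 3.47e-09; adjusted p = 0.795 with an estimated correlation), and 0 of 22 passed over the list alone. The inducible chaperone Hspa1a was at 39.9 and 40.0 in enriched ethanol replicates 1 and 2 and at 7.95 in replicate 3, against 9.14 to 10.7 in standard ethanol mice. The adhesion molecule Icam1 was at 15.6, 13.6 and 2.64 in the same 3 libraries, against 2.33 to 3.43 in the other 9 libraries. Inflammatory genes averaged 0.36 and glucocorticoid response genes 0.09 (camera adjusted p = 0.0419 and 0.0452; adjusted p = 0.795 with an estimated correlation for each). Neither call held without enriched ethanol replicate 1 (0.142 for each), enriched ethanol replicate 2 (0.125 and 0.140) or standard ethanol replicate 1 (0.140 and 0.0766), nor the glucocorticoid call without standard ethanol replicate 3 (0.232). Without enriched ethanol replicate 3 the inflammatory mean was 0.57, the glucocorticoid mean 0.17, the myelin mean -0.39 and the precursor mean -0.38. Myelin markers averaged -0.23, precursor markers -0.24 and mitochondrially encoded genes -0.14 (camera adjusted p = 2.54e-04, 0.00218 and 0.0419; adjusted p = 0.795 with an estimated correlation for each). The myelin call did not hold without enriched ethanol replicate 1 (0.0792), the precursor call without enriched ethanol replicate 2 (0.125), and the mitochondrial call without standard ethanol replicate 1 (0.629) or enriched ethanol replicates 1 (0.0952) or 2 (0.0876), with a mean of -0.21 without standard ethanol replicate 3.

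limma called 1 gene for enrichment in ethanol mice, ENSMUSG00000118641, which was listed at 0 in all enriched ethanol libraries, with 833 genes at an unadjusted p under 0.05. The genes next in order did not pass (limma adjusted p = 0.595 for each): Gm12854, Dcun1d3, the co-chaperone Fkbp4, Gm6741 and Pakap on the higher side, and Nrbp2, Plagl1, Gm6710 and Tcerg1l on the lower side. Arc, Bdnf, Nr4a1, Gfap, Egr1, Npas4, Dcx, Fos and Mbp had log2 fold changes of 0.41, 0.24, 0.16, 0.03, -0.04, -0.09, -0.10, -0.12 and -0.20, and Ttr -1.15 with an SE of 1.70. Without enriched ethanol replicate 3, 21 genes were called, and 2 without standard ethanol replicate 2 or enriched ethanol replicate 2.

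Averaged over saline and ethanol mice, which takes in the saline libraries already described, clock genes had opposite signs. In ethanol mice alone the clock list averaged -0.04 with 0 of 18 passing over the list alone (camera adjusted p = 0.545, and 0.902 with an estimated correlation). That mean cannot show whether the shift was absent there, since members that move in opposite directions cancel in it. In the average Dbp had a log2 fold change of -0.54 (SE 0.08; limma adjusted p = 0.0588) and Arntl of 0.53 (SE 0.08; limma adjusted p = 0.0760). Adjusted over the list of 18 alone, Dbp, Ciart, Nr1d1, Nr1d2, Per2 and Per3 fell and Arntl rose, and none passed over all genes (list mean -0.15, camera adjusted p = 0.00108; adjusted p = 0.695 with an estimated correlation). Over the list alone, Man1a, Mpped1 and Wfs1 of the list of 8 CA1 pyramidal cell markers rose, with a list mean of 0.17 (camera adjusted p = 0.0122; adjusted p = 0.688 with an estimated correlation), a call that did not hold without standard saline replicate 1 (0.108) or standard ethanol replicate 3 (0.0513). The chaperone genes Calr, Hspa8 and Hsp90b1 rose over the list of 22 alone (log2 fold changes 0.33, 0.18 and 0.25), with a list mean of 0.21 (camera adjusted p = 9.28e-07; adjusted p = 0.688 with an estimated correlation). Relative to the 12-library mean the list was at 0.36 and 0.40 in enriched ethanol replicates 1 and 2, at -0.11, 0.11, -0.09 and -0.06 in the other 4 enriched libraries and at -0.16 to -0.04 in standard cages. Myelin markers averaged -0.23, mitochondrially encoded genes -0.18 and striatal markers 0.27 (camera adjusted p = 3.97e-07, 1.53e-04 and 0.00108; adjusted p = 0.695, 0.688 and 0.145 with an estimated correlation), with mt-Co3 of 13 mitochondrial genes falling over the list alone, and fry gave an adjusted p of 0.0141 for the striatal markers. The myelin mean was -0.15 and the mitochondrial mean -0.12 without standard saline replicates 1 and 3 respectively. Ependymal markers averaged -0.23 (camera adjusted p = 0.0388; adjusted p = 0.695 with an estimated correlation), and -0.37 without enriched saline replicate 2. That call did not hold without standard saline replicates 1 (0.108) or 3 (0.0618), standard ethanol replicate 1 (0.101), enriched saline replicates 1 (0.0602) or 3 (0.360) or enriched ethanol replicates 1 (0.128) or 2 (0.0724). Slc6a13, a transporter gene, rose over the meningeal fibroblast list of 13 alone, and that list averaged 0.27 (camera adjusted p = 0.0154; adjusted p = 0.695 with an estimated correlation), or 0.41 without standard saline replicate 1. It was not called without standard saline replicate 2 (0.141), standard ethanol replicate 2 (0.0880), enriched saline replicate 2 (0.0834) or enriched ethanol replicate 1 (0.0997). Precursor markers averaged -0.12 and astrocyte markers -0.07 (camera adjusted p = 0.0388 and 0.0368; adjusted p = 0.695 with an estimated correlation for each). Neither call held without standard saline replicate 1 (0.180 and 0.294), standard ethanol replicates 2 (0.0880 and 0.0673) or 3 (0.0607 and 0.0513) or enriched ethanol replicates 1 (0.103 and 0.0584) or 2 (0.255 and 0.0721). The precursor call also did not hold without enriched saline replicates 1 (0.0675) or 2 (0.0697), nor the astrocyte call without standard saline replicate 3 (0.0618), while the astrocyte mean was -0.11 without standard saline replicate 2 and the precursor mean -0.19 without enriched ethanol replicate 3. limma called Gm12854, Gm44922 and ENSMUSG00000118641, with 1190 genes at an unadjusted p under 0.05, and Gm29394, Gm11027 and Cyb561 followed without passing (limma adjusted p from 0.0726 to 0.218). The count was 12 without enriched ethanol replicate 3, 10 without standard saline replicate 2 and 7 without enriched ethanol replicate 2.

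Mice with both ethanol and enrichment were compared with mice that had neither. Rbm3, a cold-inducible RNA-binding protein (chromosome X, 8138975 to 8145880), fell from 245 ± 11.3 in standard saline to 146 ± 16.7 in enriched ethanol mice (log2 fold change -0.75, SE 0.09; limma adjusted p = 0.0205). Standard ethanol mice lay between them at 187 ± 12.8 and enriched saline mice at 180.2 ± 16.8. Its relative Cirbp was at 71.1 to 74.3 in enriched ethanol and 90.7 to 100.3 in standard saline libraries. In the unfolded protein and heat shock list 6 of 22 genes rose over the list alone (Hsph1, Calr, Hspa8, Hsp90b1, Hsp90aa1 and Hspd1). The list mean was 0.34 (camera adjusted p = 3.41e-09, and 0.518 with an estimated correlation). Relative to the 12-library mean this list was at 0.36 and 0.40 in enriched ethanol replicates 1 and 2 and at -0.06 in replicate 3, against -0.16 to -0.08 in standard saline mice. Each of the 6 genes was higher in replicate 3 as well than in any standard saline library, as with Hsph1 at 180.4 against at most 162.7. In the neurogenesis list Sox11, Dcx and Dpysl3 rose and Hes5 fell over the list alone (list mean 0.24, camera adjusted p = 2.57e-04; adjusted p = 0.475 with an estimated correlation). Icam1 and Vcam1 rose over the inflammatory list of 13 alone, Ifit3 fell over the interferon list alone, and Dbp and Ciart fell over the clock list alone (list means 0.41, -0.18 and -0.16; camera adjusted p = 0.0141, 0.00512 and 0.00602; adjusted p = 0.629 with an estimated correlation for each). None of these 3 calls held without standard saline replicate 3 (0.0662, 0.0874 and 0.107), nor the inflammatory call without enriched ethanol replicates 1 (0.0784) or 2 (0.0557), the interferon call without standard saline replicate 1 (0.0638) or the clock call without enriched ethanol replicate 3 (0.252). The inflammatory mean was 0.62 without enriched ethanol replicate 3, and the interferon mean -0.30 without standard saline replicate 2. limma called Rbm3 and Gm44922, with 974 genes at an unadjusted p under 0.05. Rps27rt, Ifit3 and Ifit3b on the lower side and Gm12854, Sox11, Hist2h3c1, Plat and Dcun1d3 on the higher side did not pass (limma adjusted p from 0.174 to 0.261). Of the fixed genes, Fos, Npas4, Arc, Egr1, Nr4a1, Bdnf, Gfap and Mbp had log2 fold changes of 0.76, 0.69, 0.63, 0.33, 0.33, 0.24, 0.05 and -0.03, and Ttr -1.48 with an SE of 1.70. Without standard saline replicate 2, Fos, Npas4, Arc, Egr1 and Nr4a1 had -0.06, 0.30, 0.16, -0.06 and -0.10. Immediate-early genes averaged 0.24 (camera adjusted p = 2.37e-05; adjusted p = 0.629 with an estimated correlation) and 0.06 without standard saline replicate 2 (camera adjusted p = 0.0986) and 0.15 without enriched ethanol replicate 2. Trpc6 fell over the list of granule cell markers alone, with a list mean of -0.24 (camera adjusted p = 0.00117; adjusted p = 0.629 with an estimated correlation) and of -0.08 without standard saline replicate 2 (camera adjusted p = 0.571). Meningeal fibroblast markers averaged 0.43 and mural cell markers 0.24 (camera adjusted p = 4.18e-04 and 0.0117; adjusted p = 0.629 with an estimated correlation for each), or 0.72 and 0.41 without standard saline replicate 1. Without standard saline replicate 2 neither call held (0.181 and 0.0866), nor the mural call without standard saline replicate 3 (0.155) or enriched ethanol replicate 1 (0.158). Cytosolic ribosomal protein genes averaged -0.06 and mitochondrially encoded genes -0.15 (camera adjusted p = 1.22e-04 and 0.0383; adjusted p = 0.763 and 0.629 with an estimated correlation). Without enriched ethanol replicate 1 neither call held (0.219 and 0.159), nor the ribosomal call without standard saline replicate 1 (0.887) or the mitochondrial call without standard saline replicate 3 (0.834) or enriched ethanol replicate 2 (0.0826). The mitochondrial mean was -0.25 without standard saline replicate 1, and the ribosomal mean was -0.10 without standard saline replicate 3 and -0.095 without enriched ethanol replicate 2.

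Rbm3 did not pass without any of the 3 standard saline libraries or without enriched ethanol replicate 1 (limma adjusted p from 0.0514 to 0.171). Nor did it pass with no filter (0.0628), with the replicate number as a block (0.113) or with only the groups compared (0.231). The count was 16 without enriched ethanol replicate 3, 6 without standard saline replicate 2, and 1 without standard saline replicates 1 or 3 or enriched ethanol replicate 1.

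The interaction asks whether enrichment acted differently after ethanol. Map7, a microtubule-associated protein, averaged 80.6 ± 6.16, 62.6 ± 2.81, 62.1 ± 1.40 and 76.9 ± 2.91 in standard saline, standard ethanol, enriched saline and enriched ethanol mice, so that the mice with 1 exposure were lower than those with neither or both (interaction 0.66, SE 0.09; limma adjusted p = 0.0700). Tcerg1l had the opposite order, with 5.99 ± 0.145, 8.58 ± 0.873, 8.49 ± 0.730 and 5.70 ± 0.262 (limma adjusted p = 0.162). Neither passed, and Gm11027, Ermp1, Rab8a, Adcyap1, Sstr1 and Marcks followed at a limma adjusted p of 0.460. limma called Gm44922 and ENSMUSG00000118641 (adjusted p = 0.00263 and 0.0418), with 1107 genes at an unadjusted p under 0.05. The count was 12 without enriched ethanol replicate 3, 7 without standard saline replicate 2, and 1 without any of standard saline replicate 1, standard ethanol replicates 2 and 3, enriched saline replicates 2 and 3 and enriched ethanol replicate 1. For the interaction camera called 8 lists, each with an adjusted p of 0.934 with an estimated correlation. Lct and Dsp of the dentate granule cell list had positive interactions and Col3a1 and Dcn of the meningeal fibroblast list negative ones when adjusted over their lists alone.

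Across the 14947 genes, which are not independent replicates, the ethanol effect in standard cages and that in enriched cages had a correlation of 0.035, where unchanged groups simulated from the spread between libraries gave 0.016 (95% of draws between -0.396 and 0.415). The enrichment effects in saline and ethanol mice had 0.056 against a simulated 0.007 (-0.406 to 0.412). The ethanol effect in standard cages and the enrichment effect in ethanol mice were opposed, with a correlation of -0.465, and the same standard ethanol libraries enter both with opposite signs. Unchanged groups gave -0.482 for that pair (95% of draws between -0.866 and 0.003). The covariance was -0.0381 against a simulated -0.0410 (-0.0703 to 0.00014). The opposition thus lay within what the shared libraries alone give, and the range is too wide to exclude a reversal of moderate size. The ethanol and the enrichment effect against the same standard saline mice had 0.480 against a simulated 0.483, with a covariance of 0.0451 against 0.0411. With 3 libraries the shared groups could not be split into parts of at least 2.

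Lists that camera called in none of the 8 comparisons included most of those for neuronal signalling. Their smallest camera adjusted p over the 8 comparisons was 0.127 for neurotrophins and growth factors, 0.239 for glutamate receptors, 0.501 for GABA signalling, 0.108 for presynaptic machinery and 0.170 for monoamine and acetylcholine receptors. It was 0.396 for ethanol metabolism and antioxidant defence, 0.0607 for retinoic acid signalling, 0.0592 for perineuronal net and extracellular matrix genes, and 0.101 for replication-dependent histones. Among cell types it was 0.233 for interneurons, 0.229 for CA2 and CA3 pyramidal cells, 0.237 for neocortex and subiculum, 0.0937 for thalamus and habenula, 0.257 for microglia and 0.0933 for blood. Nuclear-encoded respiratory chain genes were called for ethanol in enriched cages, with a mean of -0.05 (camera adjusted p = 0.0126; adjusted p = 0.749 with an estimated correlation), and of 0.01 without enriched ethanol replicate 1 (camera adjusted p = 0.841). That call also did not hold without enriched saline replicates 1 (0.119) or 2 (0.341), and the mean was -0.08 without enriched saline replicate 3 or enriched ethanol replicate 2.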

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

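The tests of explanations and the exact permutation of the list mean were chosen after the results were seen, and the interaction test and the splits of the libraries were planned.

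The interaction test, which asks whether the effect of enrichment differed between saline and ethanol mice, called 2 genes and 8 lists. Chance was not excluded for either count: 10 of 100 splits of the libraries gave as many genes and 67 as many lists, and the gene count was 0 with a pseudocount of 0.1 or a mean of at least 5. Gm44922 (limma adjusted p = 0.00263) was listed above 0 in standard saline mice and at 0 in the other 3 groups. ENSMUSG00000118641 (limma adjusted p = 0.0418) was listed above 0 in standard ethanol mice and at 0 in the other groups. The dentate granule cell markers had an interaction mean of 0.47 (camera adjusted p = 2.44e-05), or 0.31 without standard saline replicate 2. The meningeal fibroblast markers had -0.69 (camera adjusted p = 1.23e-04), or -0.43 without that library. Postsynaptic density genes had 0.15 (camera adjusted p = 0.00112, and 0.0619 without standard saline replicate 3), or 0.26 without standard saline replicate 1. The circadian clock list had 0.22 (camera adjusted p = 0.0118), and was not called without standard saline replicate 3, enriched saline replicate 2 or enriched ethanol replicate 2 (0.0816, 0.0935 and 0.0596). Endothelial markers had -0.26 (camera adjusted p = 0.0136), and were not called without standard saline replicate 3, enriched saline replicate 3 or enriched ethanol replicate 2 (0.0816, 0.146 and 0.0776). The unfolded protein and heat shock list had 0.25 (camera adjusted p = 0.0223), or 0.40 without enriched ethanol replicate 3, and was not called without standard saline replicate 1 (0.108), standard ethanol replicate 1 (0.172), enriched saline replicate 3 (0.146) or enriched ethanol replicates 1 (0.0871) or 2 (0.163). The choroid plexus list had -1.19 (camera adjusted p = 0.0243), and 0.17 without enriched saline replicate 2 (0.718) and -1.83 and -1.91 without enriched saline replicates 1 and 3, and was not called without standard saline replicates 1 (0.0772) or 3 (0.0628), standard ethanol replicate 1 (0.277) or enriched ethanol replicate 2 (0.0596). The glucocorticoid response list had 0.12 (camera adjusted p = 0.0345), or a mean of 0.195 without enriched ethanol replicate 3 (camera adjusted p = 8.88e-04), and was not called without standard saline replicates 1 (0.109) or 3 (0.0816), standard ethanol replicates 1 (0.0935) or 3 (0.103), enriched saline replicates 2 (0.0574) or 3 (0.234) or enriched ethanol replicates 1 (0.0771) or 2 (0.0799). Each of the 8 lists had an adjusted p of 0.934 with an estimated correlation.

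The adult neurogenesis list averaged 0.25 higher on the log2 scale in ethanol mice over both housings, with 7 of 23 members rising and Hes5 falling over the list alone (camera adjusted p = 0.118 with an estimated correlation; exact permutation p = 0.190 adjusted over the 38 lists). In enriched cages alone it was not called without enriched saline replicate 2 or enriched ethanol replicate 3 (camera adjusted p = 0.148 and 0.296). The tables argue against standard saline replicate 2 as the whole source, since the difference without it was 0.23 (0.225, SE 0.039). In standard cages they also argue against a larger share of dentate tissue in the ethanol dissections. There the granule cell markers differed by -0.38, or -0.22 without that library. In enriched cages a larger share stays open, since the granule cell mean was -0.004 in ethanol and -0.098 in saline mice, relative to the mean of all libraries. Averaged over housing, these markers differed by -0.14 (-0.143, SE 0.109), or -0.06 without standard saline replicate 2. Chance, litter, hour of killing and other shifts in tissue stay open, as myelin, mural and precursor markers averaged 0.30, 0.22 and 0.16 as well, and an effect of early ethanol may account for the pattern only as a hypothesis found on these libraries, which mice of other litters would have to test.

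A set of 12 clock genes, called output genes here, and 4 genes of an Arntl arm moved apart in enriched saline mice. The gap was -0.82 on the log2 scale. The name output genes is loose, since Per1, Per2, Per3, Cry2, Nr1d1, Nr1d2, Bhlhe40 and Bhlhe41 were in that set with Dbp, Tef, Hlf and Ciart. The arm was Arntl, Clock, Npas2 and Nfil3. Cry1 and Rorb of the clock list were in neither set, and the sets were chosen after the values were seen. Enriched saline replicate 2 did not make the gap, which was -0.77 (-0.771, SE 0.234) without it. The Arntl arm differed by 0.33 (0.334, SE 0.091) and the output genes by -0.48 (SE 0.145). These values are for saline mice, and the gap was not computed in ethanol mice. Another hour of killing and an effect of housing on the clock could both give opposite movements, and cannot be told apart because the hour of each mouse is not given.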

How the results depend on the processing

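Some alternatives were chosen after seeing the data. These were protein-coding genes only, the exact permutation of list means and leaving out standard saline replicate 2 and enriched saline replicate 2 together. Leaving out enriched saline replicate 2 in comparisons without its group was also chosen then. The other alternatives, with each library left out in turn, were planned. Gene counts follow the order ethanol in standard cages, enrichment in saline mice, enrichment in ethanol mice, ethanol in enriched cages, both against neither, interaction, ethanol averaged, enrichment averaged, and with the settings reported were 2, 4, 1, 0, 2, 2, 2 and 3. They were 0, 4, 0, 2, 2, 0, 0 and 2 with a pseudocount of 0.1, and 2, 1, 1, 0, 2, 2, 2 and 3 with a pseudocount of 1. With no filter on low values they were 7, 7, 2, 1, 2, 4, 6 and 6, and with a mean of at least 5 they were 0, 1, 0, 0, 1, 0, 0 and 0, since most called genes are low. Median-ratio scaling gave the reported counts, and robust empirical Bayes gave 2, 2, 1, 0, 2, 2, 2 and 4. Only the groups compared gave 4, 8, 4, 1 and 2 for the first 5. Protein-coding genes only gave 0, 1, 0, 0, 1, 0, 0 and 0, and leaving out both standard saline replicate 2 and enriched saline replicate 2 gave 7, 10, 2, 1, 8, 0, 0 and 9. Leaving out 1 library gave 2 to 7, 1 to 20, 1 to 21, 0 to 15, 1 to 16, 1 to 12, 1 to 10 and 2 to 12. Except where construction is named, the cause was not tested.

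With the replicate number as a block the gene counts were 2, 3, 1, 0, 1, 2, 1 and 2, and 3 lists were called for enrichment in ethanol mice, against 6. The numbers do not pair the libraries: the 18 same-numbered pairs had correlations from -0.151 to 0.058, 0 of them over 0.1, and 2 of 12 libraries correlated best with their own number. Lists called, in the same order, were 10, 10, 6, 12, 11, 8, 13 and 10. An estimated correlation called 0 lists in each comparison, and fry called 1, 1, 0, 0, 0, 0, 1 and 1. Without both named libraries 11 lists were called for enrichment in ethanol mice and 7 for both against neither. Leaving out 1 library gave 7 to 10, 9 to 14, 3 to 9, 8 to 14, 8 to 15, 4 to 13, 10 to 16 and 7 to 16 lists. Of the list values, 1260 kept direction and side of the threshold, 351 were no longer called and 11 reversed; of the gene values 6207 kept both, 42 came to pass, 85 no longer passed and 63 changed sign, in 28 genes and comparisons, with none passing either way. The reversed means, with the other end of their range, were ribosomal proteins without standard saline replicate 1 (0.017 for ethanol in standard cages and 0.009 for both against neither, -0.093 and -0.101 without standard saline replicate 3), respiratory chain genes for ethanol in enriched cages without enriched ethanol replicate 1 (0.006, and -0.081 without replicate 2), and the choroid plexus list for enrichment in saline mice, ethanol in enriched cages, the interaction and ethanol averaged (-0.542, 0.217, 0.174 and 0.130 without enriched saline replicate 2, 1.538, -1.864, -1.906 and -0.911 without enriched saline replicate 3, and -0.511, 0.217, 0.142 and 0.145 without both named libraries). Correlations of effects ran from -0.010 to 0.065 for ethanol between housings, -0.005 to 0.085 for enrichment between treatments and -0.581 to -0.402 for the opposed pair. The adjusted p of Rbm3 ran from 0.00812 to 0.231 over all alternatives. A model with Xist as covariate and a transcript-level test were not run, since the table has no such values. Depth is unknown, so what it limits was not measured.

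Genes that changed sign had not passed, and the fixed genes make up most of them. Leaving out 1 library, the ranges were, for ethanol in standard cages Arc -0.248 to 0.527, Bdnf -0.065 to 0.099, Egr1 -0.015 to 0.621, Gfap -0.069 to 0.071, Mbp -0.043 to 0.346, Nr4a1 -0.267 to 0.468, Ttr -1.591 to 0.388. They were, for enrichment in saline mice Arc -0.573 to 0.203, Cldn2 -0.193 to 1.954, Egr1 -0.341 to 0.295, Fos -0.154 to 1.163, Nr4a1 -0.279 to 0.447, Ttr -1.29 to 2.94. They were, for enrichment in ethanol mice Egr1 -0.201 to 0.121, Fos -0.545 to 0.174, Gfap -0.026 to 0.069, Npas4 -0.534 to 0.252, Nr4a1 -0.135 to 0.347, Ttr -1.864 to 0.114. They were, for ethanol in enriched cages Bdnf -0.08 to 0.147, Fos -0.18 to 0.383, Npas4 -0.232 to 0.12. They were, for both against neither Egr1 -0.058 to 0.579, Fos -0.061 to 1.255, Gfap -0.04 to 0.1, Mbp -0.246 to 0.143, Nr4a1 -0.104 to 0.622. Without both standard saline replicate 2 and enriched saline replicate 2 the reversed values were, for ethanol in standard cages Arc -0.248, Egr1 -0.015, Gfap -0.069, Mbp -0.043, Nr4a1 -0.267, for enrichment in saline mice Cldn2 -0.261, Egr1 -0.144, Nr4a1 -0.148, Ttr -1.311, and for ethanol in enriched cages Fos -0.13. They were, for both against neither Egr1 -0.058, Fos -0.061, Gfap -0.04, Nr4a1 -0.104, and for ethanol averaged Kl 0.037. The cause was not tested.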

Other observations

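The tests of explanations in the next paragraph were chosen after the values were seen, whereas the counts over other splits of the libraries were planned.

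Single genes, chosen after their values were seen, were high in enriched ethanol replicates 1 and 2 and near the other libraries in replicate 3, among them Hspa1a, Icam1 and Vcam1. In replicates 1, 2 and 3 the cholesterol hydroxylase gene Ch25h was at 9.92, 9.94 and 0.55, the chemokine gene Cxcl1 at 12.5, 7.93 and 0.17, the kinase gene Sgk1 at 143.9, 150.4 and 51.4, and Hspb1 at 25.8, 24.6 and 6.67. More vessel cells are argued against, since the higher endothelial mean of the 2 libraries was -0.01 (-0.012, SE 0.066 over members), while Icam1 lay at least 1.68 above its 12-library mean on the log2 scale. Stimulation or handling before the tissue was taken may still account for the pattern: the immediate-early mean was 0.18 (0.176) in replicate 1 and 0.30 in replicate 2, against at most 0.19 in the other libraries, so that 1 of the 2 lay above them all. No biological explanation was tested, since the labels do not part replicate 3 from the rest of its group.

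Calls were also counted over other splits of the same libraries. For the 5 comparisons of 2 groups there are 10 splits, too few for a share under 0.05. Ethanol in standard cages gave 2 called genes, as did 2 of the 10 splits counting the real one, with 2 the highest of the others. Enrichment in saline mice gave 4, as did 2 splits (highest other 4), enrichment in ethanol mice 1, with at least as many in 7 splits (highest other 4), ethanol in enriched cages 0, with at least as many in 10 splits (highest other 3), and both against neither 2, as in 2 splits (highest other 2). For lists, in the same order, the real splits gave 10, 10, 6, 12 and 11 calls, at least as many came in 4, 8, 5, 5 and 7 splits, and the highest others were 17, 16, 12, 13 and 15.

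For the interaction and the averages 100 splits were drawn, and chance was not excluded for any count. The interaction gave 2 genes, with at least as many in 10 splits (highest other 3), and 8 lists, with at least as many in 67 (highest other 16). Ethanol averaged over housing gave 2 genes, with at least as many in 18 splits (highest other 15), and 13 lists, with at least as many in 29 (highest other 19). Enrichment averaged over ethanol gave 3 genes, with at least as many in 7 splits (highest other 7), and 10 lists, with at least as many in 55 (highest other 18). The split with 15 genes called several times the real count, while the median of the other splits was 0. It may reflect a structure of the samples or be an extreme among the draws, which was not tested.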
